A study of Mus musculus with 12 samples.

How the data were processed

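White adipose tissue of male mice was profiled on 12 Affymetrix whole-transcript arrays of 1 colour, 1 array per sample. The labels give 18-week-old animals, wild type (WT) or carrying a knockout of Ahnak (KO), fed regular chow or a high fat diet (HFD) with 60% fat, 20% carbohydrate and 20% protein for 12 weeks. Every array was placed in 1 of 4 groups of 3 arrays by its own labels: WT on chow, KO on chow, WT on HFD and KO on HFD. The labels number the replicates and do not say that each came from a separate animal, so the p-values measure only the spread between these samples. The labels also do not name the fat depot or the hour of collection.

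Per the labels' protocols, total RNA was amplified and labelled with biotin by the array maker's whole transcript sense target procedure, and the submitters' processing notes name the tool affy without a version. The background correction, summarization and normalization are not given in the sources used here. The authors deposited 1 value table for the series with 34760 rows, 1 for each probe set, and 12 columns on a log2 scale. The base was inferred from the values, which run from 2.09 to 14.2: only base 2 keeps the highest value within the range of a 16-bit scanner. No value lies below 0. The array medians lie between 5.78 and 5.92 and the 75th percentiles between 8.09 and 8.18, so the arrays had been scaled to each other, by a method that stays unknown. The values were not centred per gene. The table holds no detection calls, so no value could be set against background.

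Rows were named through the platform annotation given with the series. It lists 22961 rows with a gene; 21640 of them have 1 symbol and 1321 have several. The other 11799 rows are unnamed here. Of the rows with 1 symbol, 21553 matched the RefSeq table of assembly GRCm38.p6 by Entrez identifier and 0 symbols needed an update. For the 954 genes with more than 1 row, the row with the highest mean over all 12 arrays stood for the gene, which left 19937 genes. The table's assembly was used only for names and for the order of genes around Ahnak, since the value table names no build.

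The values were used as deposited, with no filter on dim rows. A linear model with a mean for each of the 4 groups was fitted to all 12 arrays in limma 3.58.1 under R 4.3.3, which leaves 8 residual degrees of freedom, with a moderated variance from eBayes. The comparisons were KO against WT on chow, KO against WT on HFD, the mean of both, HFD against chow in WT, HFD against chow in KO, and the interaction of genotype and diet. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 19937 genes. Changes are differences of group means on the log2 scale with the standard error (SE) of the fit.

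The groups, comparisons, gene lists, alternatives and the rule for named genes were set down before the data were examined. The 32 gene lists hold 21 pathways and 11 sets of cell type markers with 625 entries, of which 583 were measured, 11 to 31 per list. Each list was tested against all other genes with camera at its preset correlation of 0.01, adjusted over the 32 lists within a comparison, and again with a correlation estimated from the data. In no comparison did a list hold its call with the estimated correlation. A test of the lists alone with fry was added after the data had been seen; it asks whether a list's genes move, on balance, to the same side, without setting them against other genes. Counts called adjusted over the list alone use a Benjamini-Hochberg adjustment within the list's own genes. The lists do not separate genes that drive a process from genes that restrain it. A list's direction is therefore not a rate of its process. The lists were macrophage, T cell, B cell, mast cell and granulocyte, endothelial, smooth muscle and pericyte, stromal progenitor, mesothelial, skeletal muscle, epididymis and male tract, mammary and salivary epithelium, adipocyte identity, adipokines, adipose expansion, AHNAK partners and relatives, branched chain amino acid catabolism, cell cycle, cholesterol synthesis, circadian clock, de novo lipogenesis, extracellular matrix, fatty acid oxidation, immediate early and heat shock, inflammatory cytokines and chemokines, insulin signalling, interferon response, lipolysis, TCA (tricarboxylic acid) cycle and respiratory chain, TGF-beta and BMP signalling, thermogenic, triglyceride synthesis and droplet, and unfolded protein response.

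Genes are named by a fixed rule. Ahnak is always named. Each pairwise comparison and the mean over both diets name the 10 genes with the largest rise and the 10 with the largest fall among those that passed and whose groups' arrays do not overlap; where fewer than 10 passed, the 10 with the smallest p are named. Predicted genes and clones (Gm and Rik names), olfactory and vomeronasal receptors and small RNAs are counted but passed over for the next gene. Each list called by camera gives its 4 members with the smallest p in the list's direction. The interaction names the genes that passed, and a fixed set of adipocyte and inflammation genes (Lep, Adipoq, Pparg, Cebpa, Fabp4, Adgre1, Cd68, Itgax, Ccl2 and Tnf) is followed in the pairwise comparisons and the mean over both diets.

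The code was tested on simulated data: for each comparison 5 runs drew values for the 19937 genes from the fitted spread and changed 200 of them. At log2 changes of 0.5, 1 and 2 it recovered 66.0%, 95.2% and 99.4% of the changed genes for KO against WT on chow. The shares were 59.1%, 94.6% and 99.7% for KO against WT on HFD, 86.3%, 96.4% and 100% for the mean over both diets, 59.7%, 95.5% and 99.1% for HFD in WT, and 63.0%, 94.0% and 99.7% for HFD in KO. The interaction recovered 20.3%, 80.3% and 96.4%. False calls made up 4.56%, 5.53%, 4.50%, 4.97%, 4.86% and 4.13% of the calls in the same order. All 20 lists shifted by a log2 change of 0.5 were called in each comparison, with 0, 2, 3, 0, 0 and 5 calls of lists that had not been shifted. The genes were drawn independently of each other. These runs therefore do not show how often lists are called falsely where genes correlate.

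Each result was recomputed under alternatives chosen in advance: without the dimmest 40% of genes, with quantile normalization, with array medians subtracted, with only the compared groups in the fit, with trend and robust settings of eBayes, with array weights, with the replicate number as a block, with the mean of all rows of a gene, with every row of the table as its own feature, and without each array in turn. Other splits of the same arrays were counted for each comparison. The effect of these choices is given in the closing section.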

Results

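Gene expression was measured in white adipose tissue of male mice that lack Ahnak, which encodes a very large scaffold protein found at the plasma membrane, and of wild-type mice, each fed regular chow or a high fat diet (HFD). The series holds 12 arrays in 4 groups of 3: WT on chow, KO on chow, WT on HFD and KO on HFD. Each array gave 34760 log2 intensities, and 19937 genes were tested. Arrays of the same group correlated across genes at r = 0.985 to 0.996; genes are not independent replicates. The first principal component held 58.1% of the variance between arrays and the second 17.2%. On the first component the 6 chow arrays lay between -31.8 and -15.6, the KO arrays on HFD between -7.78 and 11.4, and the WT arrays on HFD between 26.4 and 57.8. Values below are log2 changes ± SE with n = 3 arrays a group, unless a mean ± SD is named.

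Ahnak itself, read by 1 row of the table, was lower on every KO array than on every WT array. Its mean log2 value was 10.03 ± 0.08 (SD, n = 3) in WT and 9.33 ± 0.08 in KO on chow, and 9.998 ± 0.30 in WT and 9.48 ± 0.10 in KO on HFD. Over both diets it fell by 0.61 ± 0.09 (adjusted p = 0.015), on HFD it fell by 0.52 ± 0.13 (adjusted p = 0.021), and the chow difference was -0.69 ± 0.13 (adjusted p = 0.38). The KO arrays kept a signal of more than 9 on the log2 scale. Whether the row's probes lie in the part of the gene that was targeted is not given in the sources used here. Diet moved it by -0.03 ± 0.13 in WT (adjusted p = 0.91) and by 0.14 ± 0.13 in KO (adjusted p = 0.55). Without WT chow replicate 1 the fall over both diets had an adjusted p of 0.051 (-0.63). The HFD call was lost without WT HFD replicate 3 (-0.50, adjusted p = 0.074), KO HFD replicate 2 (-0.48, 0.062) or KO HFD replicate 3 (-0.51, 0.067), and with only the compared groups in the fit (adjusted p = 0.099).

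**Figure D1:**
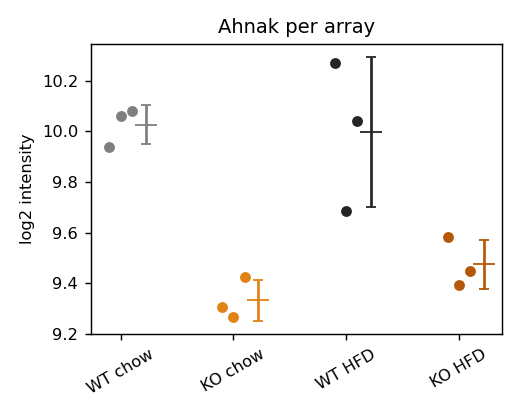
Log2 intensity of Ahnak on each of the 12 arrays (points), with the mean and SD of each group of 3 (bar). The y axis does not start at 0; every KO array lies below every WT array, with group means of 10.03 and 9.33 on chow and 9.998 and 9.48 on HFD.

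The comparison of KO with WT on chow asks what the loss of Ahnak changes without the dietary load. No single gene passed: limma called 0 of 19937 genes, with 1116 at an unadjusted p under 0.05 against 996.8 under no difference, and 0 in every other setting tried. The lowest adjusted p was 0.22, for Pyroxd2 (0.57 ± 0.08). The other genes with the smallest p were Ddx17, an RNA helicase (-0.46 ± 0.07), Tkt, the transketolase of the pentose phosphate pathway (0.56 ± 0.09), Rab15, a small GTPase (-0.99 ± 0.17), Arrdc3, an arrestin domain protein (-1.22 ± 0.21), then C8g, a subunit of complement (0.43 ± 0.07), and Ahnak. Next came the long noncoding RNA Malat1 (-0.63 ± 0.12), the stress gene Ddit4 (-1.28 ± 0.24) and Ogt, the O-GlcNAc transferase (-0.43 ± 0.08), at adjusted p of 0.32 to 0.38. Of all genes, 11.5% had arrays of KO and WT that did not overlap, where chance gives 10%. A difference as large as that of Ddit4 (-1.28) did not pass, so the 0 calls do not exclude changes of that size.

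As groups, 6 of the 32 fixed lists stood apart from the other genes on chow by camera, 2 higher and 4 lower in KO. De novo lipogenesis, the enzymes that build fatty acids from acetyl-CoA, lay higher (median 0.24 over 17 genes, adjusted p = 6.9e-07, and adjusted p = 0.35 with an estimated correlation). In it 0 genes passed over all genes and 4 rose when adjusted over the list alone: Tkt, Elovl6, which elongates fatty acids (1.24 ± 0.28), Slc25a1, the mitochondrial citrate carrier (0.44 ± 0.14), and Acly, the ATP citrate lyase (0.69 ± 0.23). The 23 genes of the TCA cycle and respiratory chain had a median of 0.12 (adjusted p = 6.9e-07, and adjusted p = 0.47 with an estimated correlation). Cox4i1 had 0.23 ± 0.07, Cox6a1 0.32 ± 0.10, Cox5a 0.28 ± 0.09 and Ndufb5 0.22 ± 0.09; none passed over all genes or adjusted over the list alone.

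Lower lists in KO on chow were immediate early and heat shock genes (median -0.30 over 18 genes, adjusted p = 4.6e-05, and adjusted p = 0.35 with an estimated correlation). None of them passed over all genes. Dusp1, a MAP kinase phosphatase (-0.72 ± 0.20), Zfp36 (-0.48 ± 0.13) and Myc (-0.60 ± 0.17) fell when adjusted over the list alone. Egr1 had -0.60 ± 0.22. The 24 macrophage markers had a median of -0.28 (adjusted p = 4.6e-05, and adjusted p = 0.47 with an estimated correlation). Mmp12, the macrophage elastase, had -1.48 ± 0.47, Ccr2 -0.65 ± 0.21, Mpeg1 -0.78 ± 0.38 and Cd5l -0.41 ± 0.21, and no member passed on either adjustment. B cell markers had a median of -0.15 over 17 genes (adjusted p = 0.00012, and adjusted p = 0.14 with an estimated correlation). Ighm had -0.37 ± 0.11, Cd79b -0.30 ± 0.10, Cd79a -0.63 ± 0.22 and Jchain -0.97 ± 0.42. The 21 inflammatory cytokines and chemokines had a median of -0.10 (adjusted p = 0.046, and adjusted p = 0.47 with an estimated correlation). Ccl8 had -0.79 ± 0.25, Ccl9 -0.43 ± 0.17, Ptgs2 -0.55 ± 0.21 and Cxcl10 -0.74 ± 0.35; in both lists 0 passed on either adjustment. By fry 2 lists passed on chow, B cell and AHNAK partners and relatives, both at an adjusted p of 0.049. The count of 6 lists became 11 without WT chow replicate 1, and the calls of 2 lists were lost without single arrays. They were immediate early and heat shock without WT chow replicate 2 (adjusted p = 0.069), and cytokines without KO chow replicate 2 or 3 or WT chow replicate 2 or 3 (adjusted p = 0.077 to 0.25). Of the fixed adipocyte genes, Lep, which encodes leptin, had -0.38 ± 0.12 (adjusted p = 0.75), while Adipoq (0.02 ± 0.14), Pparg (0.01 ± 0.15), Cebpa (0.10 ± 0.13) and Fabp4 (-0.04 ± 0.07) lay near 0.

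On HFD, KO adipose tissue had far less macrophage RNA signal than WT. Of 24 macrophage markers 19 fell and 5 did not pass (19 fell when adjusted over the list alone), with a median of -1.48 (camera adjusted p = 2.4e-16, and adjusted p = 0.25 with an estimated correlation). Mmp12 fell by 4.28 ± 0.47 (adjusted p = 0.0032). Gpnmb, a glycoprotein of lipid-laden macrophages, fell by 3.77 ± 0.50 (0.0044). Itgax, an integrin subunit of adipose macrophages and dendritic cells, fell by 3.70 ± 0.46 (0.0038), and Ctss, a lysosomal protease, fell by 1.80 ± 0.23 (0.0043). The pan-macrophage genes Cd68 (-1.89 ± 0.30) and Adgre1 (-1.62 ± 0.33) fell as well. The mean of Cd68 was 12.2 in WT and 10.3 in KO on HFD, against 10.2 and 9.9 on chow. These calls rest on a spread pooled over all 12 arrays, though that of Itgax and Cd68 was widest in WT on HFD. With only the compared groups in the fit, 1 gene was called lower, so at most 1 marker passed.

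**Figure D2:**
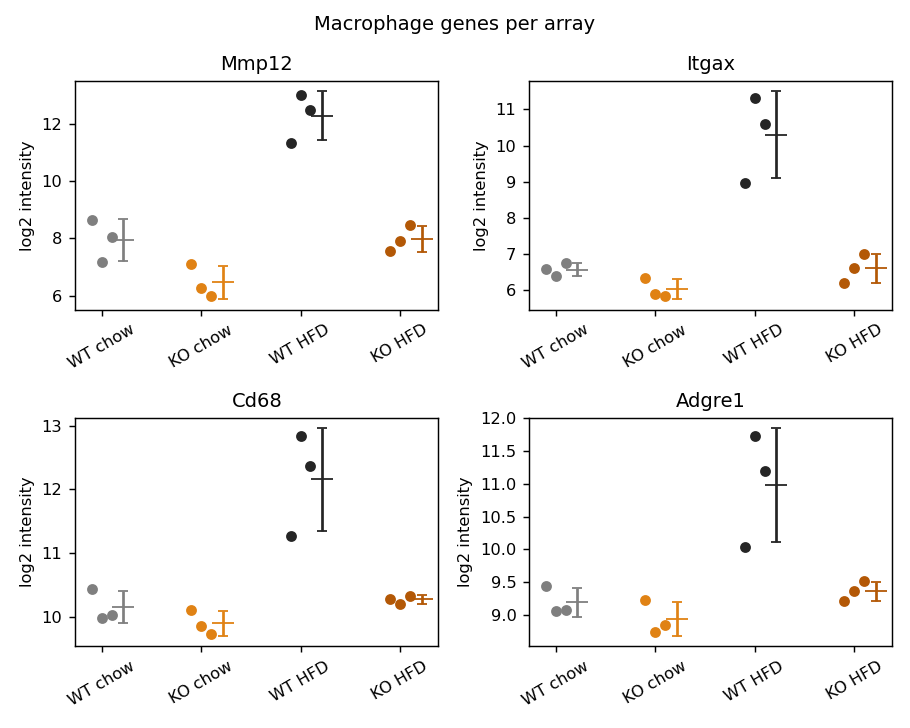
Log2 intensity of 4 macrophage genes (Mmp12, Itgax, Cd68 and Adgre1) on each of the 12 arrays (points), with the mean and SD of each group of 3 (bars). The y axes do not start at 0. The 3 WT arrays on HFD lie above all 9 other arrays for each gene, and KO differed from WT on HFD by -4.28 for Mmp12 and -1.89 for Cd68.

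In all, limma called 2691 genes for KO against WT on HFD, 1325 higher and 1366 lower; 79 were higher and 384 lower by over 2-fold. The largest falls, beside Mmp12, Gpnmb and Itgax, were in Atp6v0d2, a subunit of the vacuolar proton pump (-4.70 ± 0.68), Gpr50 (-4.58 ± 0.61), Tm4sf19 (-4.55 ± 0.62) and the ubiquitin-like gene Ubd (-3.74 ± 0.60). Rgs1, a regulator of G protein signalling (-3.62 ± 0.54), the interleukin receptor Il7r (-3.52 ± 0.56) and the adaptor Stap1 (-3.36 ± 0.62) followed (adjusted p of 0.0032 to 0.0083). Leaving out predicted genes and clones, the largest rises were in Acsm3, a mitochondrial acyl-CoA synthetase (2.73 ± 0.47), Dennd2d (2.44 ± 0.33), Fam13a (2.15 ± 0.48), Morn4 (2.04 ± 0.16) and the fatty acid elongase Elovl7 (1.98 ± 0.35). Next came Agt, which encodes angiotensinogen (1.91 ± 0.45), Mogat1, a monoacylglycerol acyltransferase (1.88 ± 0.47), Nnat (1.81 ± 0.36), the adhesion receptor Adgrg2 (1.78 ± 0.46) and Inmt (1.71 ± 0.36), at adjusted p of 0.00052 to 0.028. Of the 2691 genes, 2664 had arrays of KO and WT that did not overlap; over all genes the share was 30.9%, where chance gives 10%. The count was 1256 and 956 without WT HFD replicates 2 and 3, and 904 and 1261 without KO HFD replicates 1 and 3. With only the 6 compared arrays in the fit it was 4 (3 higher and 1 lower), and with array weights 7648.

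Other lists moved with the macrophage markers on HFD. Of 22 cell cycle genes 20 fell and 2 did not pass over all genes, and all 22 fell when adjusted over the list alone (median -1.04, adjusted p = 2.6e-18, and adjusted p = 0.29 with an estimated correlation). Examples are the mitotic kinesin Kif11 (-1.62 ± 0.22), Top2a, the topoisomerase of dividing cells (-1.72 ± 0.26), the proliferation marker Mki67 (-1.54 ± 0.24) and the kinase Aurkb (-1.0 ± 0.14). Of 25 extracellular matrix genes 15 fell and 10 did not pass, and 20 fell when adjusted over the list alone (median -0.61, adjusted p = 2.0e-12, and adjusted p = 0.25 with an estimated correlation). Col6a3, a collagen chain (-1.34 ± 0.15), Timp1, an inhibitor of metalloproteinases (-2.46 ± 0.45), Tnc, tenascin C (-1.23 ± 0.23), and Col4a2 (-0.61 ± 0.11) fell. Among 21 inflammatory cytokines and chemokines 8 fell, 1 rose and 12 did not pass (9 fell and 1 rose when adjusted over the list alone; median -0.26, adjusted p = 3.3e-05, and adjusted p = 0.25 with an estimated correlation). The acute phase gene Saa3 fell by 2.66 ± 0.37, Ccl8 by 1.62 ± 0.25, Ccl2, the monocyte chemoattractant, by 1.43 ± 0.25 and Ccl9 by 1.10 ± 0.17, while Tnf had -0.44 ± 0.19 (adjusted p = 0.17). The cell cycle count was 13 without WT HFD replicate 3 or without KO HFD replicate 1, the cytokine count 5 without either, and the matrix count 7 to 9 without KO HFD replicates 1 or 3 or WT HFD replicates 2 or 3. The macrophage count was 14 or more without any array. With only the compared groups in the fit, at most 1 member of these lists fell.

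For KO against WT on HFD 17 of 19 genes of branched chain amino acid catabolism rose and 2 did not pass, and 18 rose when adjusted over the list alone (median 0.66, adjusted p = 2.0e-12, and adjusted p = 0.33 with an estimated correlation). Bckdhb and Bckdha, subunits of the branched chain ketoacid dehydrogenase, rose by 1.58 ± 0.16 and 0.68 ± 0.13, Mccc2 by 0.86 ± 0.16 and Acad8 by 0.51 ± 0.09. In the TCA cycle and respiratory chain list 10 of 23 rose and 13 did not pass (13 rose when adjusted over the list alone; median 0.23, adjusted p = 7.4e-05, and adjusted p = 0.48 with an estimated correlation). Ndufv1 had 0.43 ± 0.10, Uqcrc2 0.29 ± 0.07, Sdha 0.40 ± 0.10 and Cox4i1 0.27 ± 0.07. Lipolysis genes rose in 4 of 11 cases and 7 did not pass (8 rose when adjusted over the list alone; median 0.35, adjusted p = 0.00019, and adjusted p = 0.35 with an estimated correlation). The phosphodiesterase Pde3b rose by 0.84 ± 0.14, perilipin Plin1 by 0.52 ± 0.10, and the triglyceride lipases Pnpla2 by 0.44 ± 0.11 and Lipe by 0.49 ± 0.12. These are RNA changes of list members and give no rate of lipolysis. Of 18 adipocyte identity genes 6 rose, 1 fell and 11 did not pass (9 and 1 when adjusted over the list alone; median 0.32, adjusted p = 0.0048, and adjusted p = 0.49 with an estimated correlation). The transcription factor Cebpa rose by 0.69 ± 0.13, Adipor2 by 0.46 ± 0.11 and Plin4 by 0.74 ± 0.19. Lep fell by 0.48 ± 0.12 (adjusted p = 0.029), and Adipoq (0.43 ± 0.14, adjusted p = 0.065), Pparg (0.29 ± 0.15) and Fabp4 (0.13 ± 0.07) did not pass. The amino acid count was 4 without KO HFD replicate 1, 5 without WT HFD replicate 3, 8 without KO HFD replicate 3 and 9 without WT HFD replicate 2. The respiratory count was 0 without KO HFD replicate 1 or WT HFD replicates 2 or 3, 1 without KO HFD replicate 3 and 3 without KO HFD replicate 2. The lipolysis count was 2 without any of KO HFD replicates 1 or 3 or WT HFD replicates 2 or 3, and the adipocyte count 2 without any KO HFD replicate or WT HFD replicate 3. On WT HFD replicates 1, 2 and 3 Bckdha lay at 10.46, 9.827 and 10.11 and Lipe at 12.43, 11.82 and 12.22. Itgax had the reverse order (8.96, 11.31 and 10.61). Bckdhb also lay higher in KO on HFD (10.54 to 11.02) than on the chow arrays (9.672 to 10.03). Whether a shift in the share of cell types in WT on HFD lies behind these rises was not tested.

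For KO against WT on HFD de novo lipogenesis had 7 of 17 genes that rose and 10 that did not pass (7 rose and 1 fell when adjusted over the list alone, median 0.22, adjusted p = 0.027, and adjusted p = 0.52 with an estimated correlation). Examples are the transcription factors Mlxipl (0.77 ± 0.13) and Srebf1 (0.70 ± 0.14), Acacb (0.88 ± 0.18) and Thrsp (1.30 ± 0.31). In triglyceride synthesis and droplet genes 5 of 17 rose, 1 fell and 11 did not pass (7 and 2 when adjusted over the list alone; median 0.20, adjusted p = 0.042, and adjusted p = 0.54 with an estimated correlation). Pck1, which supplies glycerol phosphate in adipocytes, had 1.68 ± 0.28, Lpin1 0.57 ± 0.12 and Dgat1 0.46 ± 0.11. Insulin signalling had 6 of 19 that rose, 1 that fell and 12 that did not pass (7 and 1 when adjusted over the list alone; median 0.15, adjusted p = 0.038, and adjusted p = 0.35 with an estimated correlation). Members that rose were the receptor substrates Irs1 (0.82 ± 0.12) and Irs2 (0.65 ± 0.18), the kinase Akt2 (0.45 ± 0.11) and the receptor Insr (0.53 ± 0.14). Among the WT HFD arrays Mlxipl, Srebf1, Acacb, Thrsp, Pck1, Lpin1 and these insulin signalling genes were highest on replicate 1 and lowest on replicate 2. Dgat1 was lowest on replicate 2 and highest on replicate 3. Whether these rises reflect a shift in the share of cell types was not tested. Of 16 circadian clock genes 7 rose, 2 fell and 7 did not pass (9 and 2 when adjusted over the list alone; median 0.51, adjusted p = 0.0049, and adjusted p = 0.29 with an estimated correlation). The clock output gene Dbp had 1.0 ± 0.11, Tef 0.93 ± 0.11, Per3 1.13 ± 0.16 and Nr1d2 0.56 ± 0.09.

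Further lists were lower in KO on HFD. Cholesterol synthesis had 6 of 17 that fell, 1 that rose and 10 that did not pass (8 and 1 when adjusted over the list alone; median -0.44, adjusted p = 4.6e-05, and adjusted p = 0.40 with an estimated correlation). Examples are Hsd17b7 (-0.69 ± 0.14), Msmo1 (-0.67 ± 0.15), Dhcr7 (-0.90 ± 0.21) and Mvd (-0.56 ± 0.14). In the unfolded protein response 5 of 18 fell, 1 rose and 12 did not pass (7 and 2 when adjusted over the list alone; median -0.16, adjusted p = 0.039, and adjusted p = 0.49 with an estimated correlation). Sdf2l1 had -0.85 ± 0.18, Atf6 -0.24 ± 0.06, the chaperone Hspa5 -0.38 ± 0.10 and Hyou1 -0.32 ± 0.09. Of 18 immediate early and heat shock genes Atf3 (-2.84 ± 0.45), Egr2 (-1.95 ± 0.45) and Fos (-1.46 ± 0.36) fell on both adjustments and 15 did not pass, such as Junb with -0.26 ± 0.11 (median -0.11, adjusted p = 0.027, and adjusted p = 0.40 with an estimated correlation). Of 17 B cell markers Cd22 (-1.11 ± 0.16), Cd37 (-1.0 ± 0.22), Cd79b (-0.43 ± 0.10) and Blnk (-1.94 ± 0.45) fell on both adjustments and 13 did not pass (median -0.12, adjusted p = 0.033, and adjusted p = 0.29 with an estimated correlation). Among the 13, the WT and KO arrays on HFD overlapped for Cd79a (4.333 to 5.195 and 4.659 to 4.741), Ighm and Jchain. On WT HFD replicates 1, 2 and 3 Blnk lay at 7.59, 9.953 and 9.29, in the order of Itgax (8.96, 11.31 and 10.61). Cd37 and Cd22 had the same order and Cd79b did not. Whether B cells were fewer was not tested. Marker lists of endothelial and stromal cells lay higher, without members that passed when adjusted over the list alone. Endothelial markers had a median of 0.38 over 16 genes (adjusted p = 0.0036, and adjusted p = 0.54 with an estimated correlation). In it Tek, an angiopoietin receptor, rose by 0.51 ± 0.14 over all genes, while Egfl7 (0.52 ± 0.18), Erg (0.52 ± 0.20) and Sox18 (0.38 ± 0.15) did not pass. Tek lay at 9.465, 8.965 and 9.418 on WT HFD replicates 1, 2 and 3, the reverse of the order of Itgax. Stromal progenitor markers had a median of 0.21 over 17 genes (adjusted p = 0.039, and adjusted p = 0.38 with an estimated correlation). Among them Gata2 rose by 0.37 ± 0.10 over all genes and Wnt10b (0.33 ± 0.12), Cd24a (0.96 ± 0.38) and Cd34 (0.22 ± 0.11) did not pass. Of the 18 lists called on HFD, 8 lost the call without at least 1 of the 6 arrays (adjusted p from 0.0505 to 0.19): B cell, de novo lipogenesis, endothelial, immediate early and heat shock, insulin signalling, stromal progenitor, triglyceride synthesis and droplet, and unfolded protein response. The arrays were KO HFD replicate 1 and WT HFD replicate 1 for B cells, KO HFD replicates 2 and 3 for de novo lipogenesis, WT HFD replicate 2 for endothelial markers and KO HFD replicates 1 and 3 for insulin signalling. They were KO HFD replicate 3 and WT HFD replicates 1 and 2 for immediate early genes, KO HFD replicates 1 and 2 and WT HFD replicate 3 for stromal progenitors, KO HFD replicates 2 and 3 and WT HFD replicate 2 for triglyceride synthesis, and KO HFD replicate 1 and each WT HFD replicate for the unfolded protein response. Member counts in these and in the cholesterol list moved by over 1.5 times as well, as to 1 for cholesterol synthesis without KO HFD replicate 1 or WT HFD replicates 2 or 3 and 2 for de novo lipogenesis without WT HFD replicate 3.

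**Figure D3:**
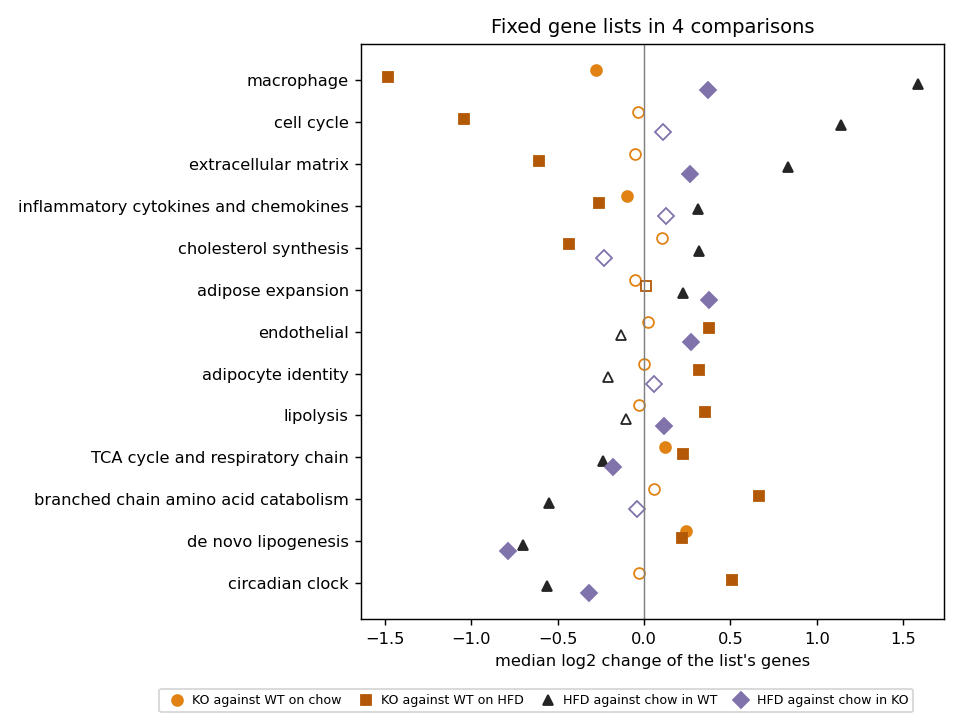
Median log2 change of the measured genes of 13 fixed lists (y axis) in 4 comparisons (x axis, log2). Filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation and open symbols the others; none holds that call with an estimated correlation. Macrophage markers lie at -1.48 for KO against WT on HFD and at 1.58 for HFD against chow in WT; these 2 comparisons share the same 3 WT arrays on HFD.

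Averaged over both diets, KO tissue differed from WT in 892 genes by limma, 352 higher and 540 lower, with 4118 at an unadjusted p under 0.05. Among the genes whose KO and WT arrays overlapped in neither diet, the largest falls were in Mmp12 (-2.88 ± 0.33), Itgax (-2.12 ± 0.32), Il7r (-2.09 ± 0.40), Rgs1 (-1.99 ± 0.38), and Tnip3 (-1.80 ± 0.25). These were followed by Slc37a2 (-1.66 ± 0.32), the pore-forming protein Mpeg1 (-1.65 ± 0.27), Lat2 (-1.51 ± 0.30) and the leukocyte receptors Lilr4b (-1.39 ± 0.28) and Lilrb4a (-1.23 ± 0.23), at adjusted p of 0.010 to 0.028. The largest rises among them were in Acsm3 (1.81 ± 0.33), Morn4 (1.41 ± 0.11), the amino acid transporter Slc43a1 (1.26 ± 0.17), Pth1r, the parathyroid hormone receptor (0.87 ± 0.12), Oscp1 (0.84 ± 0.13), and the lactate receptor Hcar1 (0.82 ± 0.15). They were followed by the vitamin transporter Slc5a6 (0.76 ± 0.12), Acaca, the acetyl-CoA carboxylase of fatty acid synthesis (0.71 ± 0.16), Eepd1 (0.71 ± 0.17) and Phkg1 (0.69 ± 0.16), at adjusted p of 0.0013 to 0.043. Morn4 was higher on every KO array than on every WT array of the same diet and kept its call in every alternative, with values of 1.33 to 1.52. Of the 892 genes, 341 had arrays that overlapped in neither diet; over all genes the share was 4.35%, where chance gives 1%. The count rested on single arrays on both sides: it was 15 without WT chow replicate 1, 274 and 241 without WT chow replicates 2 and 3, and 274, 121 and 229 without KO chow replicates 1, 2 and 3. It was 2621, 490 and 91 without WT HFD replicates 1, 2 and 3, and 105, 385 and 125 without KO HFD replicates 1, 2 and 3. It was 361 with the replicate number as a block, 163 with every row tested and 3909 with array weights.

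By list, 14 of 24 macrophage markers fell over both diets and 10 did not pass (19 fell when adjusted over the list alone; median -0.85, adjusted p = 8.8e-18, and adjusted p = 0.17 with an estimated correlation). Ctss had -1.10 ± 0.16, Gpnmb -2.28 ± 0.36, Cd68 -1.07 ± 0.22 and Adgre1 -0.94 ± 0.23. Cell cycle genes fell in 11 of 22 cases and 11 did not pass (19 fell when adjusted over the list alone; median -0.55, adjusted p = 2.0e-15, and adjusted p = 0.28 with an estimated correlation). Bub1b had -0.58 ± 0.11 and Kif11 -0.83 ± 0.16. In the extracellular matrix 7 of 25 fell and 18 did not pass (14 when adjusted over the list alone; median -0.31, adjusted p = 1.1e-10, and adjusted p = 0.17 with an estimated correlation). Examples are Col6a3 (-0.65 ± 0.10), Col4a2 (-0.42 ± 0.08) and Col4a1 (-0.41 ± 0.09). Of the cytokines 5 of 21 fell and 16 did not pass (8 fell and 1 rose when adjusted over the list alone; median -0.23, adjusted p = 6.4e-06, and adjusted p = 0.17 with an estimated correlation). Ccl8 had -1.20 ± 0.18, Saa3 -1.63 ± 0.26, Ccl9 -0.77 ± 0.12 and Ccl2 -0.77 ± 0.17. Immediate early genes Atf3 (-1.50 ± 0.32), Fos (-1.08 ± 0.25) and Myc (-0.48 ± 0.12) fell and 15 of 18 did not pass (5 fell when adjusted over the list alone; median -0.19, adjusted p = 8.1e-05, and adjusted p = 0.17 with an estimated correlation). B cell markers Cd79b (-0.37 ± 0.07), Cd22 (-0.55 ± 0.11) and Cd37 (-0.65 ± 0.15) fell on both adjustments and 14 of 17 did not pass (median -0.22, adjusted p = 0.00021, and adjusted p = 0.17 with an estimated correlation). Among 17 AHNAK partners and relatives Anxa1 (-0.35 ± 0.07), an annexin, and Myof (-0.80 ± 0.16), which encodes myoferlin, fell and 15 did not pass, such as Ahnak2 with -0.58 ± 0.15 (3 fell when adjusted over the list alone; median -0.02, adjusted p = 0.028, and adjusted p = 0.17 with an estimated correlation). These counts of fallen genes rested on single arrays. The macrophage count was 1 without WT chow replicate 1, 5 without WT HFD replicate 3, and 6 to 9 without WT chow replicate 2 or 3, KO chow replicate 2 or 3 or any KO HFD replicate. The cell cycle count was 0 without WT chow replicate 1, WT HFD replicate 3, any KO chow replicate or KO HFD replicate 1 or 3. It was 1 to 7 without WT chow replicate 2 or 3, WT HFD replicate 2 or KO HFD replicate 2, and 19 without WT HFD replicate 1. The matrix count was 0 to 3, and the immediate early count 0 or 1, without any 1 array other than WT HFD replicate 1. The cytokine count was 9 without WT HFD replicate 1, 0 without WT chow replicate 1, and 3 without any other array except WT chow replicate 3 and KO HFD replicate 2. The B cell count was 0 or 1 without any 1 array other than WT HFD replicates 1 and 2 and KO HFD replicate 2. That of the AHNAK partners was 4 without WT HFD replicate 1, and 0 or 1 without any other array except WT HFD replicate 2 and WT chow replicate 3.

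Over both diets de novo lipogenesis had 5 of 17 that rose and 12 that did not pass (9 when adjusted over the list alone; median 0.43, adjusted p = 1.9e-05, and adjusted p = 0.28 with an estimated correlation). Tkt had 0.43 ± 0.06, Mlxipl 0.46 ± 0.10 and Srebf1 0.44 ± 0.10. The TCA cycle and respiratory chain list had 4 of 23 that rose (15 when adjusted over the list alone; median 0.17, adjusted p = 3.7e-08, and adjusted p = 0.33 with an estimated correlation). Cox4i1 had 0.25 ± 0.05 and Sdhb 0.24 ± 0.06. Branched chain amino acid catabolism had 3 of 19 that rose (18 when adjusted over the list alone; median 0.34, adjusted p = 7.4e-11, and adjusted p = 0.29 with an estimated correlation), namely Bckdhb (0.83 ± 0.11), Bckdha (0.41 ± 0.09) and the kinase Bckdk (0.28 ± 0.06). Clock genes rose in 4 and fell in 2 of 16 cases (8 and 2 when adjusted over the list alone; median 0.25, adjusted p = 0.019, and adjusted p = 0.28 with an estimated correlation). Dbp had 0.67 ± 0.08 and Nr1d2 0.38 ± 0.06. Of the remaining lists, adipocyte identity had 2 that rose and 1 that fell of 18 (3 and 1 when adjusted over the list alone; median 0.17, adjusted p = 0.028, and adjusted p = 0.57 with an estimated correlation). Lipolysis had 0 of 11 (3 rose when adjusted over the list alone; median 0.12, adjusted p = 0.0029, and adjusted p = 0.38 with an estimated correlation). Endothelial markers had 0 of 16 on either adjustment (median 0.18, adjusted p = 0.028, and adjusted p = 0.65 with an estimated correlation). Cholesterol synthesis had 1 that fell, Hsd17b7 (-0.39 ± 0.10), and 1 that rose of 17 (3 and 1 when adjusted over the list alone; median -0.23, adjusted p = 0.011, and adjusted p = 0.56 with an estimated correlation). The unfolded protein response had 2 of 18 that fell, Atf6 (-0.19 ± 0.04) and Sdf2l1 (-0.52 ± 0.13) (5 fell and 2 rose when adjusted over the list alone; median -0.11, adjusted p = 0.011, and adjusted p = 0.38 with an estimated correlation). Lep fell by 0.43 ± 0.09 and Cebpa rose by 0.40 ± 0.09. These counts rested on single arrays too. Without WT HFD replicate 1 they were 14 for the respiratory list, 18 for amino acid catabolism, 7 for adipocyte identity and 4 for cholesterol synthesis. Without any other array the respiratory and adipocyte identity counts were 0 or 1. Amino acid catabolism had 0 or 1 without any of the others except WT HFD replicate 2 and KO HFD replicate 2, and cholesterol synthesis 0 without any of them except WT chow replicate 3 and KO HFD replicate 2. Lipogenesis had 0 to 3 without any 1 array other than WT HFD replicates 1 and 2, and the unfolded protein response 0 or 1 without any 1 other than WT HFD replicate 1. The clock count was 1 or 2 without WT chow replicate 1, WT HFD replicate 3, KO chow replicate 2 or KO HFD replicate 1 or 3. Calls were lost without KO chow replicate 2 or KO HFD replicate 2 or 3 for adipocyte identity (adjusted p of 0.062 to 0.16) and without WT chow replicate 2 for cholesterol synthesis (0.095) and the unfolded protein response (0.061). The endothelial call was lost without KO chow replicate 3, KO HFD replicate 2 or either of WT chow and WT HFD replicate 2 (0.0504 to 0.35), and that of the AHNAK partners without KO chow replicate 3, KO HFD replicate 2 or WT HFD replicate 1 (0.0504 to 0.069).

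In WT mice 4802 genes were called by limma for the high fat diet against chow, 2345 higher and 2457 lower on HFD, with 491 higher and 445 lower by over 2-fold. The largest rises were in Gpr50 (4.47 ± 0.61), the choline transporter Slc5a7 (4.45 ± 0.41), Tm4sf19 (4.44 ± 0.62), Atp6v0d2 (4.42 ± 0.68), Mmp12 (4.32 ± 0.47), and Ubd (3.97 ± 0.60). After these came the gastric lipase Lipf (3.79 ± 0.47), Itgax (3.73 ± 0.46), Rgs1 (3.58 ± 0.54) and Gpnmb (3.51 ± 0.50), at adjusted p of 0.00037 to 0.0018. The largest falls were in Cuzd1 (-5.36 ± 0.90), Dcdc2a (-4.67 ± 0.81), Bbox1, the last enzyme of carnitine synthesis (-4.08 ± 0.80), Cyp2f2 (-4.07 ± 0.59) and the metalloproteinase Mmp7 (-3.92 ± 0.77). Behind them stood Iyd (-3.68 ± 0.60), Plet1 (-3.65 ± 0.78), Clic6 (-3.49 ± 0.61), Epcam, the epithelial cell adhesion molecule (-3.46 ± 0.60), and Kcnk1 (-3.33 ± 0.61), at adjusted p of 0.0015 to 0.0071. The leptin gene Lep rose by 0.88 ± 0.12, Cebpa fell by 0.62 ± 0.13, and Adipoq (-0.27 ± 0.14), Pparg (-0.37 ± 0.15) and Fabp4 (-0.05 ± 0.07) did not pass. Of the 4802 genes, 4698 had arrays of both diets that did not overlap; over all genes the share was 38.8%, where chance gives 10%. With array medians subtracted the split was 3366 higher and 1527 lower (68.8% higher, against 48.8%), as the median of all genes then lay at 0.07 instead of -0.03. The count was 3072 without WT HFD replicate 3 and 9985 with array weights.

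Of 24 macrophage markers 19 rose in WT on HFD and 5 did not pass (20 rose when adjusted over the list alone; median 1.58, adjusted p = 1.3e-11, and adjusted p = 0.26 with an estimated correlation). Itgam rose by 1.53 ± 0.20, Ctss by 1.68 ± 0.23, Cd68 by 2.01 ± 0.30 and Adgre1 by 1.79 ± 0.33. Beside them, 20 of 22 cell cycle genes rose and 2 did not pass (22 when adjusted over the list alone; median 1.14, adjusted p = 1.1e-14, and adjusted p = 0.35 with an estimated correlation). Examples are Top2a (1.97 ± 0.26), Kif11 (1.73 ± 0.22) and Tpx2 (1.73 ± 0.26). Of 25 extracellular matrix genes 20 rose and 5 did not pass (23 when adjusted over the list alone; median 0.83, adjusted p = 2.6e-14, and adjusted p = 0.24 with an estimated correlation). Examples are the collagen chains Col6a3 (1.59 ± 0.15), Col6a2 (1.19 ± 0.16), Col6a1 (1.02 ± 0.14) and Col5a1 (0.83 ± 0.10). Of 21 cytokines and chemokines 8 rose and 13 did not pass (9 when adjusted over the list alone; median 0.31, adjusted p = 0.00024, and adjusted p = 0.26 with an estimated correlation). Saa3 had 2.63 ± 0.37, Ccl2 1.76 ± 0.25, Ccl7 1.46 ± 0.21 and Ccl9 1.18 ± 0.17; Tnf rose by 0.59 ± 0.19 (adjusted p = 0.044). Cholesterol synthesis had 6 of 17 that rose, 1 that fell and 10 that did not pass, on both adjustments (median 0.32, adjusted p = 0.0033, and adjusted p = 0.58 with an estimated correlation). Dhcr7 had 1.26 ± 0.21 and Hmgcs1 0.90 ± 0.18. The count was 3 without WT chow replicate 3 or WT HFD replicate 3. The unfolded protein response had 9 of 18 that rose, 3 that fell and 6 that did not pass (10 and 3 when adjusted over the list alone; median 0.28, adjusted p = 0.0062, and adjusted p = 0.41 with an estimated correlation). Sdf2l1 had 1.19 ± 0.18 and Edem1 0.61 ± 0.10.

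Fatty acid synthesis genes fell in WT on HFD in 9 of 17 cases and 8 did not pass (10 when adjusted over the list alone; median -0.70, adjusted p = 4.8e-05, and adjusted p = 0.36 with an estimated correlation). Acaca fell by 1.48 ± 0.22, Acacb by 1.37 ± 0.18, Srebf1 by 0.93 ± 0.14 and Tkt by 0.76 ± 0.09. Branched chain amino acid catabolism fell in 14 of 19 genes and 5 did not pass (15 when adjusted over the list alone; median -0.55, adjusted p = 9.0e-08, and adjusted p = 0.41 with an estimated correlation). Bcat2, the mitochondrial aminotransferase, had -0.94 ± 0.15 and Bckdha -0.69 ± 0.13. In the clock list 11 of 16 fell, 2 rose and 3 did not pass, on both adjustments (median -0.56, adjusted p = 4.8e-05, and adjusted p = 0.24 with an estimated correlation). Per3 fell by 1.72 ± 0.16, Dbp by 1.36 ± 0.11, Tef by 1.32 ± 0.11 and Per2 by 1.13 ± 0.12. The TCA cycle and respiratory chain list had 12 of 23 that fell, 1 that rose and 10 that did not pass (15 and 2 when adjusted over the list alone; median -0.24, adjusted p = 0.00014, and adjusted p = 0.58 with an estimated correlation). Ndufv1 had -0.52 ± 0.10 and Sdhb -0.44 ± 0.08. The count was 7 without WT HFD replicate 2. Triglyceride synthesis and droplet genes fell in 7 of 17 cases, rose in 2 and did not pass in 8 (8 and 2 when adjusted over the list alone; median -0.26, adjusted p = 0.025, and adjusted p = 0.62 with an estimated correlation). Pck1 had -1.32 ± 0.28 and Cidea -1.02 ± 0.18. Adipose expansion genes, which track fat mass, rose in 7 of 16 cases, fell in 2 and did not pass in 7 (8 and 2 when adjusted over the list alone; median 0.23, adjusted p = 0.013, and adjusted p = 0.36 with an estimated correlation). Examples are Peg3 (2.04 ± 0.36), Sfrp5 (1.90 ± 0.29) and Bmp3 (1.21 ± 0.14). Of 17 AHNAK partners and relatives 7 rose, 3 fell and 7 did not pass (7 and 4 when adjusted over the list alone; median 0.21, adjusted p = 0.038, and adjusted p = 0.26 with an estimated correlation). Examples are the annexins Anxa1 (0.74 ± 0.09), Anxa2 (0.67 ± 0.10) and Anxa5 (0.57 ± 0.07), and Ahnak2 (1.42 ± 0.22). Interferon response genes Ifit2 (0.54 ± 0.12), Oas1a (0.65 ± 0.18) and Oas3 (0.44 ± 0.14) rose, 1 fell and 13 of 17 did not pass, on both adjustments (median 0.19, adjusted p = 0.049, and adjusted p = 0.41 with an estimated correlation). The call of the adipose expansion list was lost without WT HFD replicate 1 (adjusted p = 0.12) and that of the triglyceride list without WT HFD replicate 2 (0.096). The call of the AHNAK partners was lost without WT HFD replicate 1 or WT chow replicate 1 (0.075 and 0.067), and that of the interferon list without either of these or WT HFD replicate 2 (0.075 to 0.16).

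In KO mice the high fat diet gave 1264 calls by limma, 559 higher and 705 lower, with 34 higher and 256 lower by over 2-fold. Among the genes whose arrays of both diets did not overlap, leaving out predicted genes, the largest rises were in Slc5a7 (2.64 ± 0.41), the matrix glycoproteins Thbs1 (2.38 ± 0.32) and Thbs2 (1.71 ± 0.27), and the imprinted genes Peg3 (2.37 ± 0.36) and Zim1 (1.81 ± 0.29). Further ones were the Wnt inhibitor Sfrp5 (2.19 ± 0.29), Jade3 (1.83 ± 0.21), Dock8 (1.75 ± 0.21), Dusp10 (1.65 ± 0.17) and Prr32 (1.59 ± 0.15), at adjusted p of 0.0014 to 0.012. The largest falls among them were in Cuzd1 (-3.84 ± 0.90), Dcdc2a (-3.63 ± 0.81), Cyp2f2 (-3.53 ± 0.59), Bbox1 (-3.42 ± 0.80), Plet1 (-3.27 ± 0.78), and Iyd (-3.04 ± 0.60). Lower down stood Adcy8 (-2.88 ± 0.58), Epcam (-2.84 ± 0.60), B4galnt2 (-2.82 ± 0.62) and Fbp1, the fructose bisphosphatase of gluconeogenesis (-2.75 ± 0.73), at adjusted p of 0.014 to 0.048. KO HFD replicate 1 stood apart. Over the 10 genes with the largest falls in WT its mean log2 value was 8.13, against 5.23 and 5.26 on the other KO HFD arrays and 8.61 to 9.94 on the chow arrays. Without that array Cuzd1 had -5.26 (adjusted p = 0.00034). Without KO HFD replicate 2 or 3 it had -3.13 and -3.14 (adjusted p = 0.10 and 0.14). Without KO chow replicate 1 or 3 it had -3.65 and -3.66 (adjusted p of 0.11 for both). The leptin gene Lep rose by 0.78 ± 0.12, and Adipoq (0.14 ± 0.14), Pparg (-0.09 ± 0.15), Cebpa (-0.03 ± 0.13) and Fabp4 (0.13 ± 0.07) did not pass. Of the 1264 genes, 1252 had arrays of both diets that did not overlap; over all genes the share was 28.8%, where chance gives 10%. With array medians subtracted the split was 1160 higher and 532 lower (68.6% higher, against 44.2%), with the median of all genes at 0.06 instead of -0.01. The count was 140 without KO chow replicate 1, 233 without KO chow replicate 3, 229 without KO HFD replicate 2 and 62 without KO HFD replicate 3. It was 585 with only the compared groups in the fit, 740 with the replicate number as a block, 2137 with array weights and 837 with every row tested.

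**Figure D4:**
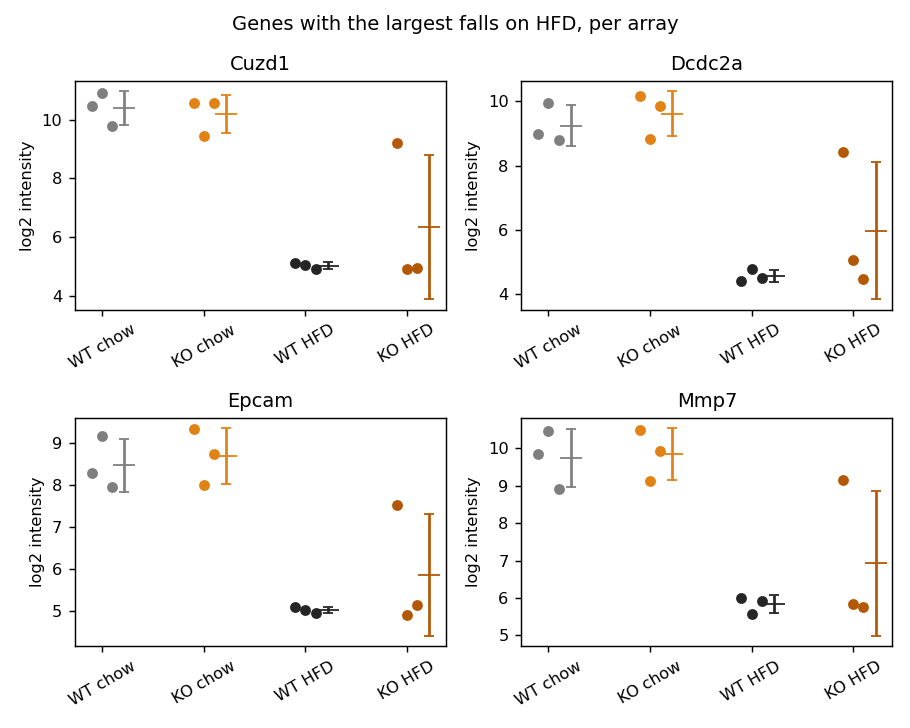
Log2 intensity of Cuzd1, Dcdc2a, Epcam and Mmp7 on each of the 12 arrays (points), with the mean and SD of each group of 3 (bars). The y axes do not start at 0. All 3 WT arrays and 2 of 3 KO arrays on HFD lie far below the chow arrays, while KO HFD replicate 1 lies near the chow level; Cuzd1 fell by 5.36 in WT and 3.84 in KO.

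None of 24 macrophage markers passed in KO on HFD on either adjustment (median 0.37, adjusted p = 0.029, and adjusted p = 0.75 with an estimated correlation). Mmp12 had 1.52 ± 0.47 (adjusted p = 0.079), Ccr2 0.51 ± 0.21, Itgam 0.37 ± 0.20, Mrc1 0.25 ± 0.14, Cd68 0.38 ± 0.30 and Ccl2 0.45 ± 0.25. De novo lipogenesis fell in 9 of 17 genes and 8 did not pass (11 when adjusted over the list alone, median -0.79, adjusted p = 3.3e-08, and adjusted p = 0.21 with an estimated correlation). Elovl6 had -1.78 ± 0.28, Tkt -1.02 ± 0.09, Slc25a1 -0.85 ± 0.14 and Me1 -0.80 ± 0.14. The count was 2 without KO chow replicate 1 or KO HFD replicate 3 and 5 without KO HFD replicate 2. Adipose expansion genes rose in 6 of 16 cases and 10 did not pass (7 when adjusted over the list alone; median 0.38, adjusted p = 2.9e-05, and adjusted p = 0.21 with an estimated correlation). Bmp3 had 0.88 ± 0.14 beside Sfrp5, Peg3 and Lep. The count was 1 without KO HFD replicate 3. Adipokine genes rose in 4 of 15 cases and 11 did not pass, on both adjustments (median 0.11, adjusted p = 0.017, and adjusted p = 0.50 with an estimated correlation). Rarres2 had 0.66 ± 0.12 and Angptl4 0.82 ± 0.17. The annexins Anxa2 (0.64 ± 0.10), Anxa5 (0.44 ± 0.07) and Anxa1 (0.59 ± 0.09) rose among 17 AHNAK partners and 14 did not pass (5 rose when adjusted over the list alone; median 0.17, adjusted p = 0.043, and adjusted p = 0.21 with an estimated correlation). In the extracellular matrix Thbs1 and Col6a1 (0.57 ± 0.14) rose and 23 of 25 did not pass (3 rose when adjusted over the list alone; median 0.27, adjusted p = 0.00031, and adjusted p = 0.50 with an estimated correlation).

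Clock genes Dbp (-0.69 ± 0.11), Ciart (-1.28 ± 0.23) and Hlf (-0.63 ± 0.16) fell in KO on HFD, 1 rose and 12 of 16 did not pass (9 fell and 1 rose when adjusted over the list alone; median -0.32, adjusted p = 0.0044, and adjusted p = 0.21 with an estimated correlation). In the thermogenic list Cidea (-0.86 ± 0.18), Slc27a2 (-2.50 ± 0.57) and Cox8b (-0.96 ± 0.24) fell on both adjustments and 15 of 18 did not pass (median -0.15, adjusted p = 0.017, and adjusted p = 0.21 with an estimated correlation). Of these, Slc27a2 went with the genes of the largest falls in WT array by array: it lay at 7.50 to 8.87 on the chow arrays, 4.54 to 5.03 on WT HFD, and 7.398, 5.123 and 5.056 on KO HFD replicates 1, 2 and 3. In the TCA cycle and respiratory chain list Cox4i1 (-0.30 ± 0.07), Cox5a (-0.41 ± 0.09) and Sdhb (-0.31 ± 0.08) fell and 20 of 23 did not pass (5 when adjusted over the list alone; median -0.18, adjusted p = 0.00012, and adjusted p = 0.63 with an estimated correlation). In the other called lists single genes rose. Stat2 rose by 0.34 ± 0.08 among 17 interferon response genes (2 when adjusted over the list alone; median 0.16, adjusted p = 0.031, and adjusted p = 0.50 with an estimated correlation). Aqp7, the glycerol channel, rose by 0.59 ± 0.13 among 11 lipolysis genes (1 on the list alone; median 0.11, adjusted p = 0.043, and adjusted p = 0.73 with an estimated correlation). Edem1 rose by 0.49 ± 0.10 among 18 unfolded protein response genes (4 when adjusted over the list alone; median 0.19, adjusted p = 0.013, and adjusted p = 0.50 with an estimated correlation). Endothelial markers had a median of 0.27 over 16 genes with 0 that passed on either adjustment, such as Cldn5 with 0.56 ± 0.16 (adjusted p = 0.013, and adjusted p = 0.75 with an estimated correlation). The calls of 5 lists in KO were lost without at least 1 array (adjusted p of 0.052 to 0.19): AHNAK partners, interferon response, lipolysis, macrophage and thermogenic. For macrophage markers these arrays were KO chow replicate 2 (0.19), KO chow replicate 3 (0.052) and KO HFD replicate 3 (0.077), and for the thermogenic list KO chow replicate 2 (0.069). They were KO chow replicate 2 and KO HFD replicate 3 for the interferon response (0.16 and 0.090), KO chow replicates 1 and 3 and KO HFD replicates 1 and 3 for lipolysis (0.056 to 0.11), and KO chow replicates 2 and 3 and KO HFD replicates 1 and 3 for AHNAK partners (0.053 to 0.071). The counts of fallen genes were 0 in the clock list without KO HFD replicate 3, 0 in the thermogenic list without KO chow replicate 1 or KO HFD replicates 2 or 3, and 0 or 1 in the respiratory list without any single array.

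The diet responses of WT and KO, which share no arrays, were then set side by side. Their calls come from the same fit of all 12 arrays, with the same estimate of each gene's spread. The calls in WT and KO are therefore not independent. Of the genes called in both, 305 rose in both genotypes and 542 fell in both, where independent lists would share 65.8 and 86.9, and 14 went opposite ways. Given the shared estimate of spread, the expected counts are only a rough yardstick. Of the 4802 genes called in WT, 84.0% changed to the same side in KO, and of the 1264 called in KO, 92.2% did so in WT. Across genes the KO change had a slope of 0.43 on the WT change by least squares through the origin (jackknife SE 0.18 over the 12 left-out arrays). The reverse slope was 0.95 and r = 0.639 across genes, which are not independent replicates. The sum of 847 shared genes was 523 without WT chow replicate 1, 440 without WT HFD replicate 3, 103 and 156 without KO chow replicates 1 and 3, and 141 and 50 without KO HFD replicates 2 and 3. It was 313 with only the compared groups in the fit, 507 with the replicate number as a block, 1595 with array weights and 486 with every row tested.

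**Figure D5:**
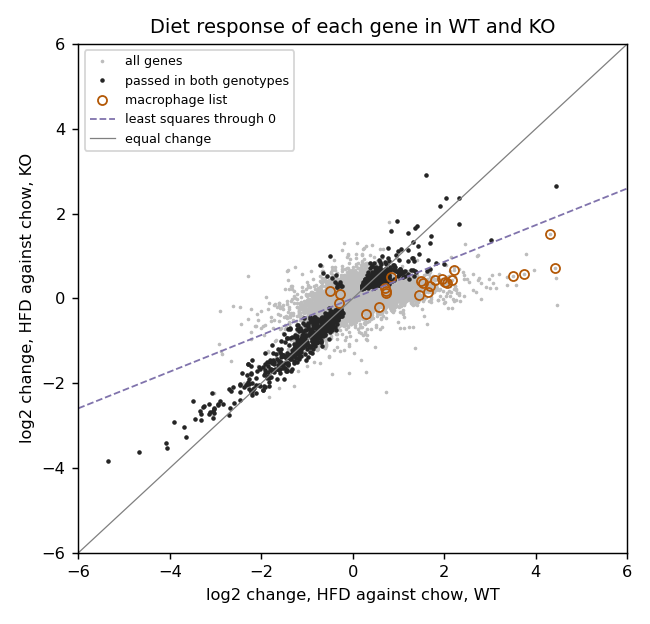
Log2 change on HFD against chow of each of 19937 genes in WT (x axis) and in KO (y axis). Dark points are the genes that passed in both genotypes, circles the macrophage list, the dashed line the least squares slope of 0.43 through the origin and the solid line equal change. Macrophage markers lie to the right, with a median of 1.58 in WT and 0.37 in KO, and the genes with the largest falls lie low in both.

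Whether the diet response differs between genotypes is tested by the interaction, KO response minus WT response. By limma 1 gene was called, Ppfibp2, a liprin scaffold gene, whose mean was 6.9 in WT and KO on chow, 8.1 in WT on HFD and 7.0 in KO on HFD (-1.12 ± 0.11, adjusted p = 0.014). In all, 3496 genes had an unadjusted p under 0.05, where 996.8 are expected. As groups 11 lists stood apart, 6 higher and 5 lower, while 0 of their genes passed over all genes. Macrophage markers had a median of -1.37 and 17 of 24 were lower when adjusted over the list alone (adjusted p = 9.1e-11, and adjusted p = 0.33 with an estimated correlation). Itgax had -3.15 ± 0.64, Mmp12 -2.80 ± 0.66, Ctss -1.39 ± 0.33 and Cx3cr1 -0.65 ± 0.15. Cell cycle genes had -1.09 and 21 of 22 were lower on the list alone (adjusted p = 4.0e-17, and adjusted p = 0.33 with an estimated correlation). Aurkb had -1.06 ± 0.20 and Kif11 -1.58 ± 0.31. The extracellular matrix had -0.65 and 11 of 25 (adjusted p = 2.7e-10, and adjusted p = 0.33 with an estimated correlation). Col6a3 had -1.37 ± 0.21 and Lum -1.22 ± 0.34. Branched chain amino acid catabolism had 0.57 and 13 of 19 higher on the list alone (adjusted p = 1.5e-10, and adjusted p = 0.36 with an estimated correlation). Bckdhb had 1.5 ± 0.23 and Mccc2 0.90 ± 0.22. The clock list had 0.32 with 8 higher and 1 lower of 16 on the list alone (adjusted p = 0.0023, and adjusted p = 0.33 with an estimated correlation). Tef had 0.97 ± 0.16 and Per3 1.22 ± 0.23. By fry 0 lists passed. The endothelial call was lost without WT HFD replicate 2 (adjusted p = 0.12), and that of insulin signalling without KO HFD replicate 1, KO chow replicate 3 or WT chow replicate 2 (0.055 to 0.067). The Ppfibp2 call was lost without WT chow replicate 1 or 3, KO chow replicate 1, or WT HFD replicate 2 or 3 (-1.14 to -1.08, adjusted p of 0.066 to 0.083), and with the replicate number as a block (adjusted p = 0.068), which left 0 genes. The count was 0 without any of these 5 arrays, 20 without WT chow replicate 2, 2060 without WT HFD replicate 1, and 2 without KO chow replicate 2 or 3 or KO HFD replicate 1 or 2. It was 84 without the dimmest genes, 2819 with array weights and 3 with every row tested.

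The 100 measured genes nearest to Ahnak, 50 on each side in the order of assembly GRCm38.p6, were compared with the other genes. Of them 5 (5%) passed for KO against WT over both diets, against 886 of 19836 other genes (4.47%; 2-sided Fisher's exact test, p = 0.81).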

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

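The tests in this part that set the diet responses of the genotypes against each other were chosen beforehand, and fry was added only after the results were seen.

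The interaction test of KO against WT diet responses called 1 gene and 11 lists. None of the 11 passed with an estimated correlation, where the lowest adjusted p was 0.33, or by fry. At least 1 gene was called in 13 of 100 splits of the arrays, the real one included. Such splits can keep the real HFD groups together, so that count does not measure chance. Ppfibp2 had an interaction of -1.12 (adjusted p = 0.014 by limma), with 3496 genes at an unadjusted p under 0.05. Without WT chow replicate 1 or 3, KO chow replicate 1 or WT HFD replicate 2 or 3 its adjusted p was 0.066 to 0.083, and with the replicate number as a block 0.068. The lists with a lower median in KO were macrophage (-1.37), cell cycle (-1.09), extracellular matrix (-0.649), cholesterol synthesis (-0.611) and inflammatory cytokines and chemokines (-0.215). Those with a higher median were branched chain amino acid catabolism (0.566), endothelial (0.381), lipolysis (0.36), circadian clock (0.32), adipocyte identity (0.277) and insulin signalling (0.164). The adjusted p with an estimated correlation was 0.38 for cholesterol synthesis, 0.36 for cytokines, lipolysis and insulin signalling, 0.57 for adipocyte identity and 0.79 for endothelial markers. In cholesterol synthesis 4 of 17 genes fell and 1 rose when adjusted over the list alone, in lipolysis 4 of 11 rose, in adipocyte identity 3 of 18 rose and in the cytokines 3 of 21 fell. The endothelial call was lost without WT HFD replicate 2 (adjusted p = 0.12). The insulin signalling call was lost without KO chow replicate 3, KO HFD replicate 1 or WT chow replicate 2 (adjusted p = 0.055 to 0.067).

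Signal also appeared in the 11799 rows that the annotation gives no gene and that the comparisons of genes leave out. With every row tested, 300 of them (2.54%) passed for KO against WT on HFD, against 8.48% of the rows with a gene. The numbers were 15 (0.127%, against 0.645%) over both diets, 637 (5.40%, against 18.4%) for HFD in WT and 162 (1.37%, against 2.94%) for HFD in KO. What these rows measure was not examined here.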

How the results depend on the processing

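The tests with fry were chosen only after the results were seen; all other settings in this part were set beforehand.

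Of the alternatives to the counts, the slope, Ahnak and its neighbours, 212 gave a similar value, 51 a weaker one, 16 a stronger one and 4 a moved one. The cause was not tested unless named. The rule for similar is wide. It takes in counts within 1.5 times of the main one, 0 beside 0 included, and slopes within the jackknife SE of 0.18. For Ahnak and its neighbours it takes in every value with the same direction and no change of call. The balance of the calls did turn: for HFD in KO 44.2% were higher, against 68.6% with array medians subtracted, 55.7% with the filter on dim genes, 57.4% with only the compared groups in the fit, 52.3% with every row tested and 36.3% to 62.9% without single arrays. For HFD in WT 48.8% were higher, against 68.8% with array medians subtracted and 46.9% to 53.7% without single arrays. For KO against WT on HFD 49.2% were higher, against 54.4% with the filter on dim genes, 45.5% with array medians subtracted and 38.1% to 50.6% without single arrays. With an estimated correlation 0 lists passed in each of the 6 comparisons, and the cause was not tested. By fry 2 lists passed on chow (6 by camera), 12 for KO against WT on HFD (18), 11 over both diets (16), 16 for HFD in WT (14), 6 for HFD in KO (13) and 0 for the interaction (11). With only the compared groups in the fit (4 residual degrees of freedom), 4 genes passed for KO against WT on HFD. The counts were 3372 for HFD in WT, 585 for HFD in KO and 313 in both genotypes. Array weights gave 7648 genes for KO against WT on HFD, 3909 over both diets, 9985 for HFD in WT, 2137 for HFD in KO and 2819 for the interaction, with 1595 called in both genotypes. Their estimation stopped before convergence and gave WT HFD replicate 3 a weight of 20.0, against 0.376 to 1.68 for the others. The weighted mean of WT on HFD therefore rests largely on that array. It does not enter the group means of HFD in KO. How far the counts depend on it was not tested. Every row tested alone gave 163 genes over both diets, 837 for HFD in KO, 3 for the interaction and 486 in both genotypes, and the filter on dim genes gave 84 for the interaction.

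Leaving out each array in turn gave these ranges. Genes numbered 904 to 3930 for KO against WT on HFD, 15 to 2621 over both diets, 3072 to 5285 for HFD in WT, 62 to 1509 for HFD in KO, 0 to 2060 for the interaction and 50 to 1021 called in both genotypes. Lists on chow numbered 5 to 11. The slope ran from 0.334 to 0.520, Ahnak over both diets from -0.69 to -0.54, and the p of the genes next to Ahnak from 0.0996 to 1, never under 0.05. Of 270 called results of named genes 90 kept the call in every alternative: 2 of 84 for KO against WT on HFD, 4 of 64 over both diets, 73 of 77 for HFD in WT, 11 of 44 for HFD in KO and 0 of 1 for the interaction.

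The replicate numbers do not pair the arrays. Correlations of residuals between arrays of the same number lay between -0.408 and 0.379, and in 0 of 6 group pairs did all exceed 0.1. With the replicate number as a replicate block the count was 361 over both diets, 740 for HFD in KO, 0 for the interaction (3267 at an unadjusted p under 0.05 by limma) and 507 in both genotypes. Not run were a log offset, because the values are already on a log scale, and a fit of only the compared groups where all 4 groups enter. The trend and robust settings do not alter the slope.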

Other observations

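The 7 tests of the patterns below and the count over Ahnak's whole chromosome were chosen only after the results were seen; the splits of the arrays were chosen beforehand.

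For KO against WT on HFD the T cell list had 1 of 17 genes that fell (median 0.13, mean -0.14), mast cell and granulocyte 1 that rose and 2 that fell of 19 (median 0.11), smooth muscle and pericyte 2 of 15 that fell (median 0.07), skeletal muscle 1 of 18 that fell (median -0.01) and mesothelial 0 of 14 (median -0.03). Fatty acid oxidation had 4 of 17 that rose and 1 that fell (8 and 1 when adjusted over the list alone, median 0.09, adjusted p = 0.070). TGF-beta and BMP signalling had 3 of 31 that rose and 2 that fell (median 0.20), and mammary and salivary epithelium 1 and 1 of 16 (median 0.08). For HFD against chow in WT fatty acid oxidation had 2 that rose and 6 that fell, TGF-beta and BMP signalling 4 and 5, and epididymis and male tract 0 of 18 (median -0.03). Of 14 mesothelial markers Krt8 (-1.84) and Krt18 (-1.61), named after their values were seen, fell on HFD in WT and the median was -0.36 (adjusted p = 0.15); in KO 2 fell as well, with a median of -0.18 (adjusted p = 0.080). Mammary and salivary epithelium had 3 of 16 that fell on HFD in each genotype and 1 that rose in WT, with medians of -0.04 and means of -0.50 in WT and -0.43 in KO. The mean of a list had another sign than the median for T cells in KO against WT on HFD as above and in WT on HFD (median -0.13, mean 0.11), for B cells in WT on HFD (median -0.23, mean 0.05) and for thermogenic genes in WT on HFD (median 0.08, mean -0.13); camera called none of these. Smooth muscle and pericyte had a median of 0.07 and a camera direction of down for KO against WT on HFD.

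Over Ahnak's chromosome, 45 of 677 measured genes (6.65%) passed for KO against WT over both diets, against 845 of 19240 elsewhere (4.39%; Fisher's exact test, p = 0.0078). Morn4 and Pyroxd2 lie on that chromosome. Genes on the same arrays are not independent replicates, so this p does not measure the spread between samples. The 892 calls behind it became 15 without WT chow replicate 1, and the test was not repeated without single arrays.

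Other splits of the same arrays were counted for each comparison. With 10 splits of 6 arrays a share under 0.05 cannot arise. In those comparisons the real count and the highest of the other splits were 0 and 66 genes for KO against WT on chow (10 of 10 splits at least as large), 2691 and 0 for KO against WT on HFD (1 of 10), 4802 and 0 for HFD in WT (1 of 10), and 1264 and 1 for HFD in KO (1 of 10). For KO against WT over both diets 2 of 100 splits reached the real 892 genes, the highest other giving 911, a share under 0.05. For the interaction 13 of 100 splits called at least the real 1 gene and the highest called 824. Splits of these 2 kinds can keep the real WT and KO arrays on HFD together and mix only the chow arrays. They then carry the HFD difference into the test. The splits therefore do not measure chance for the interaction, and the share over both diets does not show a difference on chow.

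Macrophage markers were lower in KO than in WT on HFD, with a median of -1.48. A lower share of every cell type other than adipocytes would lower endothelial markers too, but their median was 0.38 (0.3752; quartiles 0.324 to 0.471, against -1.9 to -0.705 for macrophages). A single WT array is argued against by the 14 markers that fell at the least without 1 WT array. With array medians subtracted the median of the macrophage markers was -1.50. The array medians lie only between 5.78 and 5.92, so subtracting them could hardly move that value. It therefore cannot decide whether scaling between arrays played a part. Fewer macrophages, or less expression per macrophage, may remain as explanations, and both stay untested.

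Of the 10 genes with the largest falls on HFD in WT only Epcam is in a fixed list, so the 10 were not tested as a kind of gene. Epididymis in the chow samples is argued against by 0 of 18 epididymis markers being lower by 1 or more on the log2 scale on HFD in WT. Loss of mesothelium as the whole cause would need its markers to fall alike. This was tested on the KO arrays, which did not serve to choose the 10 genes: the median of the markers was -0.178 (quartiles -0.653 to -0.07), against quartiles of -3.5 to -2.86 for the 10 genes, which argues against it. A smaller loss stays open. KO HFD replicate 1, whose 10-gene mean of 8.13 lies near the chow arrays, had an adipose expansion score of 0.259, which argues against a chow array with the wrong label (chow -0.312 to -0.172). Another tissue taken along with the fat might be a source and was not tested, nor was an effect of diet on the cells that express the 10 genes.

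Clock genes were lower in WT on HFD than on chow, while Arntl, which is expressed in the opposite phase to Dbp, rose by 1.20 (adjusted p = 0.0020). That is consistent with a different hour of collection, and Arntl in KO against WT on HFD had -1.19 (adjusted p = 0.0059). Nr1d1, another gene of the same loop, had -0.11 (adjusted p = 0.81). The hour is not given in the labels, so it cannot be separated from an effect of diet or genotype on the clock.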
